A study of Mus musculus with 2 samples.

How the data were processed

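Ribosome-reduced total RNA from the left cerebral cortex of 2 female B6CASTF1/J mice was measured by RNA sequencing, 1 library per animal. Per the labels, each library was built from 300 ng of RNA with a directional (stranded) library kit and ERCC spike-ins. The labels number the animals 1 and 5 but give both the same donor entry, so the animals are taken as separate from their numbers alone. Both libraries carry the same strain, sex, age range and tissue and were placed in 1 group, with the replicate number given in the labels. No sequencing date or batch is used here.

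Per the deposited readme text, reads were mapped to genome build mm10 with the GENCODE M21 annotation. The aligner, the quantification tools and their versions are not given in the sources used here. Each library had a gene table and a transcript table with the column layout that RSEM writes (the first table), and another transcript table with the layout that kallisto writes (the second table). Expected counts in the first table are the authors' estimated counts per feature, in which a read that fits several features is shared out, and they were not normalized. Estimated counts in the second table are deposited per transcript in the same way. TPM values, also deposited, are scaled by the authors to the same total over all features, spike-ins included. The percent of a gene's TPM in each transcript is given per the file headers. The model's credibility bounds and posterior SD of each count are deposited scores without a fixed range, and their level is not stated.

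The gene table held 55536 genes, 26248 tRNA features, 96 ERCC spike-ins and 1 phiX feature. Effective lengths were 100 nt below annotated lengths, so 2452 genes and 26185 tRNA features had an effective length of 0, and all tRNA features had 0 counts. Shares depend on the unit: 7SL took 3.20% of counts and 25.3% of TPM. A further 86 genes off the main chromosomes are not in the second table. Reads of the hybrid were assigned on the reference genome, so reads of CAST/EiJ sequence may be counted less often, and alleles were not analysed here. Spike-in concentrations were not used here. Whether counting used strand is not given in the sources used here, so antisense genes such as Tsix are uncertain.

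Total expected counts were 28327434 for replicate 1 and 30234441 for replicate 2. Spike-ins had 75029 and 68108 counts, from 65 and 61 detected species. The median counting SE of a log2 difference was 0.0835 over 14122 genes.

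Levels are mean ± SD of deposited TPM over the 2 animals. Genes were called detected at 1 TPM or more in both libraries. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, scaled with TMM factors, and turned into log2 CPM (counts scaled by library size) with a prior count of 1. A log2 difference is replicate 2 minus replicate 1 for genes with a mean of at least 50 counts. The biological coefficient of variation came from edgeR's common dispersion, with an intercept only. No test across animals was run, since 1 group of 2 animals has no contrast. Spike-in scaling gave a ratio of effective library sizes, replicate 2 over replicate 1, of 0.908, against 1.10 for TMM, 1.09 for DESeq2 1.42.0 size factors and 1.07 for totals. Large values are given to 4 significant digits.

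Gene lists were written before the data were examined, as were the results, the alternatives in the plan and the rule for named genes. The 41 lists cover cell classes (excitatory, inhibitory, interneuron subclass, upper and deep layer neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial, mural, meningeal, choroid plexus, ependymal and red blood cells) and other regions (striatum, hippocampus, thalamus, olfactory bulb, hypothalamus). They also cover states (immediate early, clock, glucocorticoid, heat shock, interferon), receptors, channels, neuropeptides, synapse, respiratory chain, neurodegeneration, imprinted, X linked, Y linked and nuclear noncoding genes, and a set of 24 isoform genes. Of the listed symbols 3 are not annotated (Rn45s, Rn7sl1 and Tac3). A list's median log2 difference was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, with limits at 2.5 and 97.5. Lists under 5 measured members have values only. Lists of endoplasmic reticulum chaperones, MAP kinase feedback genes, clock phases and cold-induced genes were added after the data were seen.

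Named genes are the 20 with the highest mean TPM and, for each list, up to 4 members with the highest TPM and up to 3 with the largest difference, plus low members of lists of other tissues, Y linked genes and receptor families. The rule also takes the 10 genes higher and 10 lower in replicate 2 with the largest log2 difference among genes with a mean of at least 200 counts and credibility intervals that do not overlap, and the isoform genes. The 20 highest were taken over all genes and over nuclear protein-coding genes. Neat1, Snhg11, Pantr1, Rian and Tsix were chosen after their values were seen.

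Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data for the comparison of replicate 2 with replicate 1. Among 17377 simulated genes, 100% of those given 3-fold and 6-fold differences and 4.48% of those given 1.5-fold differences passed the 2-fold limit, as did 1 of 13889 unchanged genes, and a coefficient of variation of 10% came back as 9.83%. The simulated spread was the same for all genes and below the 12.7% of the data, without errors of read assignment. These rates therefore do not carry over to the real genes. Of 100 simulated lists of 15 genes without a shift 4 lay outside the limits, and 20 of 20 shifted by 0.5 did. Alternatives covered scaling, count and TPM minimums, prior count, pseudocount, mean in place of median, the second table, rescaled TPM and leaving out each replicate. A cubic trend on transcript length and GC content, and a restriction to genes on which the tables give close differences, were added after the data were seen.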

Results

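Total RNA was sequenced from the left cerebral cortex of 2 adult female mice, aged 8 to 10 months. The animals were B6CASTF1/J, the F1 hybrid of the inbred strains C57BL/6J and CAST/EiJ. Each library was made from 300 ng of ribosome-reduced total RNA with added ERCC spike-ins, which are synthetic transcripts. Replicate 1 came from animal 1 and replicate 2 from animal 5, and together they form the only group. The gene tables held 28327434 estimated read counts for replicate 1 and 30234441 for replicate 2. The design sets no treatment against a control, so the questions are which genes the cortex expressed, at what level, and how far the animals differed. Levels are TPM, the length-scaled share of all transcripts, given as mean ± SD over both animals, and a log2 difference is always replicate 2 minus replicate 1.

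Among nuclear protein-coding genes the highest level belonged to Gapdh, a glycolytic enzyme, at 1443 ± 2.40 TPM (SD, n = 2). Snap25, a SNARE protein of synaptic vesicle fusion, reached 1312 ± 77.2 TPM, and Camk2a, the alpha subunit of a calcium-dependent kinase of excitatory synapses, 1108 ± 84.4 TPM. Mbp, which encodes myelin basic protein, stood at 917 ± 46.9 TPM and Glul, the glutamine synthetase of astrocytes, at 1084 ± 35.9 TPM. Others among the 20 highest were Fth1, Aldoa, Actb, Eef1a1, Calm2, Snurf, Ptgds, Cpe, Cst3, Syp, Ubb, Calm3, Hspa8 and Ckb, from 1312 down to 868 TPM. Snurf, at 1052 ± 34.1 TPM in the first table, had 0 TPM in the second, so its level is uncertain.

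Over all annotated genes the top places went to structural and mitochondrial RNAs. Rn7s1 and Rn7s2, the copies of the 7SL RNA of the signal recognition particle, had 126300 ± 8776 TPM each (SD, n = 2), with their shared reads divided equally. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 followed at 57500 ± 904 and 41930 ± 1476 TPM, and Rn7sk, the 7SK RNA that restrains transcription elongation, at 34640 ± 1791 TPM. Gm26917, annotated as a lincRNA, reached 10740 ± 134 TPM, and the origin of its reads was not checked. The cytochrome oxidase gene mt-Co1 reached 7422 ± 416 TPM. The pseudogenes of mitochondrial genes on chromosome 1, Gm28661, Gm10925, Gm29216 and Gm28437, are near-identical to mitochondrial sequence, and their levels of 8562, 5375, 4682 and 2627 TPM are therefore uncertain. The nuclear noncoding RNA Malat1 stood at 3856 ± 1301 TPM (2161 TPM in the second table), and mt-Co3, Rpph1, mt-Cytb, mt-Nd1, Rmrp, mt-Atp6, Gm42418 and mt-Nd3 completed the 20. By counts, nuclear protein-coding genes took 80.6 ± 0.0873% of each library, mitochondrial genes 9.52 ± 0.0359% and 7SL 3.20 ± 0.282%. Spike-ins took 0.245 ± 0.0280% of the counts.

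At 1 TPM or more in both animals, 14889 of 55536 annotated genes were detected (26.8%), and 12971 of 22028 protein-coding genes (58.9%). Detection was rarer among noncoding classes, with 285 of 5854 lincRNAs, 183 of 2959 antisense genes and 462 of 9941 processed pseudogenes. The median protein-coding level was 16.5 ± 0.460 TPM over 12958 nuclear genes (SD, n = 2). In both animals 1005 genes exceeded 100 TPM and 40 exceeded 1000 TPM. Of 1536 genes that reached 1 TPM in a single animal, 1469 stayed below 5 TPM there. At these depths 3 counts of a transcript of 1 kb equal 0.165 TPM in replicate 1 and 0.159 TPM in replicate 2. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

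Markers of every neuronal class on the lists were detected, with list medians of 77.1 TPM for excitatory, 30.1 TPM for interneuron subclass, 25.8 TPM for upper layer and 14.7 TPM for deep layer markers. The inhibitory median of 11.0 TPM includes a second Dlx6os1 entry at 0 TPM and is therefore too low to rank against the others. Without that entry it lies between the levels of Adarb2 (10.7 TPM) and Erbb4 (30.9 TPM). Excitatory neurons were represented by Slc17a7, the vesicular glutamate transporter of cortical neurons, at 469.9 ± 24.95 TPM (SD, n = 2) and by Nrgn, a calmodulin-binding postsynaptic protein, at 669 ± 19.4 TPM. Of the inhibitory markers, Gad1, which makes GABA, stood at 247 ± 3.29 TPM and Gad2 at 72.9 ± 2.62 TPM. Interneuron subclass markers were led by the peptide genes Cck at 262 ± 18.5 TPM and Sst at 199 ± 20.9 TPM, ahead of Lamp5 at 99.8 ± 5.28 TPM. The tissue was measured in bulk, so these levels cannot be assigned to interneurons alone. Upper layer markers (layers 2 to 4) included Rasgrf2 at 86.6 ± 2.16 TPM and Cux2 at 77.3 ± 14.3 TPM. Deep layer markers (layers 5 and 6) included Bcl11b at 47.7 ± 0.941 TPM and Etv1 at 29.4 ± 1.08 TPM.

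Every glial and vascular class on the lists was detected. Slc1a2, the main astrocytic glutamate transporter, reached 825 ± 29.6 TPM (SD, n = 2), and Aldoc, a glycolytic enzyme enriched in astrocytes, 360.4 ± 25.9 TPM. The myelin gene Mobp stood at 222 ± 7.97 TPM, and Olig1, a transcription factor of the oligodendrocyte lineage, at 44.4 ± 1.22 TPM. Microglial genes were lower, with Csf1r, the receptor that microglia need to survive, at 34.5 ± 0.580 TPM and the complement gene C1qb at 26.8 ± 0.269 TPM. The endothelial tight junction gene Cldn5 had 18.7 ± 1.67 TPM and the pericyte gene Rgs5 20.2 ± 1.56 TPM. Of the meningeal fibroblast markers, Ptgds, a prostaglandin synthase that oligodendrocytes also express, reached 1019 ± 156 TPM and the growth factor gene Igf2 42.9 ± 5.96 TPM. The haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 stood at 169 ± 16.5, 168 ± 27.3 and 146 ± 8.39 TPM. The Hba-a1 and Hba-a2 sequences are near-identical, so their division is uncertain. In the second table the red blood cell list had a median of 82.1 TPM, against 145.8 TPM in the first.

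Marker genes of other brain regions separated into a high striatal list and low remaining lists. Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, had 294.5 ± 22.1 TPM (SD, n = 2), the opioid peptide gene Penk 215.5 ± 15.4 TPM and the phosphodiesterase gene Pde10a 106 ± 5.22 TPM. The median over the 10 striatal markers was 55.2 TPM. It was 1.64 TPM over the 8 hippocampal markers, where Prox1 led at 5.21 ± 0.127 TPM, and 5.23 TPM over the 8 thalamic and habenular markers, where Rora led at 34.0 ± 1.54 TPM. Olfactory bulb markers had a median of 0.653 TPM, with Cdhr1 at 7.37 ± 0.778 TPM and Slc6a3, the dopamine transporter gene, at 0.04 TPM. Hypothalamic markers had a median of 1.09 TPM, from 1.49 TPM in replicate 1 and 0.695 TPM in replicate 2, with the vasopressin gene Avp at 3.79 ± 0.502 TPM and the hypocretin gene Hcrt at 0.055 TPM. The ependymal median was 1.58 TPM, led by Rarres2 at 8.15 ± 0.0636 TPM. Among choroid plexus markers, the thyroid hormone carrier gene Ttr had 172 TPM in replicate 1 and 55.7 TPM in replicate 2.

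Receptor, channel and synapse genes were expressed broadly. Among GABA-A subunits Gabra6, typical of cerebellar granule cells, had 0.11 TPM. Gria2, the AMPA receptor subunit that limits calcium entry, stood at 212 ± 14.8 TPM (SD, n = 2) and Gria1 at 129 ± 6.27 TPM. The obligatory NMDA receptor subunit gene Grin1 had 172 ± 22.3 TPM, and Grin3b 0.115 TPM. Grm5 led the metabotropic glutamate receptors at 90.9 ± 0.240 TPM, and the retinal receptor gene Grm6 had 0.02 TPM. Chrm1, a muscarinic acetylcholine receptor, led its list at 64.6 ± 3.79 TPM, with Drd4 at 0.24 TPM. The sodium channel genes Scn2a and Scn2b stood at 139 ± 9.43 and 137 ± 3.45 TPM, and the potassium channel genes Kcna2 and Kcnc1 at 73.4 ± 2.94 and 68.5 ± 5.47 TPM. Medians over presynaptic and postsynaptic density genes were 215 ± 9.90 and 129 ± 11.1 TPM, with Syp at 969.9 ± 8.58 TPM and Dlg4, which encodes PSD-95, at 395 ± 9.91 TPM.

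The nuclear encoded respiratory chain list had a median of 172 ± 4.83 TPM (SD, n = 2), with the ATP synthase subunit gene Atp5b at 865 ± 12.3 TPM and Cox4i1 at 545 ± 19.2 TPM. Genes associated with neurodegeneration included Apoe, the lipid carrier of astrocytes, at 824 ± 24.8 TPM, App, the amyloid precursor, at 643 ± 42.0 TPM and Clu at 412 ± 5.08 TPM. Interferon responsive genes were low, with a median of 1.46 TPM, led by Ifi27 at 36.6 ± 1.10 TPM. Imprinted genes, expressed from a single parental copy in at least some tissues, were led by Snurf, Gnas at 818 ± 17.4 TPM and the maternally expressed noncoding RNA Meg3 at 817 ± 273 TPM. Parental copies were not separated here. Xist, the RNA that silences an X chromosome in females, had 20010 counts in replicate 1 and 24516 in replicate 2. The Y linked genes had at most 2 counts in the first table, with Ddx3y at 2 in each library, Kdm5d at 1 and 0, and Uty and Eif2s3y at 0 in both, where 3 counts would equal 0.042 to 0.141 TPM. In the second table their median was 0.447 TPM, with Uty at 1.11 TPM and Kdm5d at 0.742 TPM, so the tables differ on these genes and their absence rests on the first.

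Across genes, levels were close in the animals, with a Pearson r of 0.992 and a Spearman rho of 0.935 over 55536 genes on the log2(TPM + 1) scale. Over 16425 genes at 1 TPM or more in either library, r was 0.976 and the median absolute log2 difference was 0.17. Genes are not independent replicates, so no p-value is attached. Counts differed by more than sampling noise, with a chi-square of 13.2 per degree of freedom over 20184 genes, so they are not 1 library deposited again. That says nothing of the donor entry that the labels share. The biological coefficient of variation was 12.7% over 17377 genes.

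Differences were ranked among genes with a mean of at least 200 counts and credibility intervals that do not overlap. The largest there were those of Gm17167, a processed transcript (log2 difference 5.70, but 2.31 in the second table), and of the pseudogene Gm5859 (4.71), both higher in replicate 2 and both uncertain, since read assignment in this region was not checked. Arc, an activity-induced regulator of synapses, had 129.5 TPM in replicate 1 and 14.5 TPM in replicate 2 (log2 difference −3.24, counting SE 0.0536), or 9.45-fold lower in replicate 2. Fos, an immediate early transcription factor gene, was 8.33-fold lower (log2 −3.06, counting SE 0.166), and Hspa5, the main chaperone of the endoplasmic reticulum, 2.77-fold lower (log2 −1.47, counting SE 0.0277). In the other direction, the clock repressor gene Ciart was 2.64-fold higher in replicate 2 (log2 1.40, counting SE 0.114) and the cold-inducible RNA-binding protein gene Cirbp 2.38-fold higher (log2 1.25, counting SE 0.0709). Arc, Fos and Hspa5 were also lower with spike-in scaling, which added 0.28 to the median log2 difference of all genes. That shift could not turn the genes higher in replicate 2.

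In build mm10, Arc (ENSMUSG00000022602.14) lies on chromosome 15 from 74669083 to 74672570, with 6944 counts in replicate 1 and 807 in replicate 2. Fos (ENSMUSG00000021250.13) lies on chromosome 12 from 85473890 to 85477273, with 643 and 84 counts. Hspa5 (ENSMUSG00000026864.13) lies on chromosome 2 from 34771970 to 34777547, with 9511 and 3777 counts. Ciart (ENSMUSG00000038550.10) lies on chromosome 3 from 95878503 to 95882251, with 212 and 617 counts. Cirbp (ENSMUSG00000045193.13) lies on chromosome 10 from 80165985 to 80172786, with 571 and 1494 counts. All 5 are annotated as protein coding.

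The 10 genes in each direction were taken among those with a mean of at least 200 counts and credibility intervals that do not overlap. The remaining 7 of the 10 genes lower in replicate 2 were Myh6, a cardiac myosin (log2 −2.19), the heat shock gene Hspa1b (−2.05), the nuclear receptor gene Nr4a1 (−1.96), the endoplasmic reticulum gene Sdf2l1 (−1.80), Ttr (−1.70), the MAP kinase phosphatase gene Dusp4 (−1.70) and the transcription factor gene Egr1 (−1.48). Hspa1b and Hspa1a are near-identical, so the share of each is uncertain. The remaining 8 of the 10 higher in replicate 2 were Gm17167, Gm5859, the ephrin receptor gene Epha8 (1.27), the signalling regulator gene Rgs11 (1.25), Zbed6 (1.10), the oligodendrocyte gene Opalin (1.06), the chloride channel gene Ano2 (1.04) and the lincRNA AI480526 (1.02). Gm17167 (ENSMUSG00000091542.1, a processed transcript) and Gm5859 (ENSMUSG00000073879.4, an unprocessed pseudogene) lie side by side on chromosome 4, from 42206998 to 42235313 and from 42236859 to 42239182. Counts of Gm17167 were 7.70 and 512, and those of Gm5859 were 14.1 and 428. The second table gave 0.51 for Zbed6, so its size and that of Gm17167 are uncertain.

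Of 14122 genes with a mean of at least 50 counts, 177 (1.25%) differed more than 2-fold, 88 higher and 89 lower in replicate 2. Scaling on spike-ins gave 292 higher and 47 lower (86.1% higher, against 49.7%). TPM credibility intervals did not overlap for 59 of the 88 and 60 of the 89. Within 1.2-fold lay 72.6% of the genes, and the central 95% of log2 differences ran from −0.57 to 0.69. With 1 library per animal, a difference between the animals has no replicate check and no p-value.

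Immediate early genes, which neurons transcribe within minutes of activity, were lower in replicate 2 in all 21 measured members, or in 20 of 21 with spike-in scaling. Their median log2 difference was −1.03, or 2.05-fold lower, at the 0.005 percentile of 10000 expression-matched random lists, the lowest that number can give. The largest after Arc and Fos was Egr2 (−2.86, 277 and 41 counts), and the abundant transcription factor gene Egr3 stood at −0.69. Heat shock genes, which encode protein-folding chaperones, were lower in 12 of 12 members, or 9 of 12 with spike-in scaling, with a median of −0.57 at the 0.005 percentile. The abundant members Hspa8 and Hsp90ab1 had log2 differences of −0.64 and −0.22, and Hspb1, a small heat shock gene, −1.31.

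Clock genes went in both directions, and their median of −0.090 lay inside the range of random lists at percentile 17.6. Ciart, Nr1d1, a clock repressor, and Dbp, a clock output factor, were higher in replicate 2 (1.40, 0.80 and 0.75). Per2, a core repressor of the clock, was lower (−1.11). Per2 was lower with every scaling tried. Against TMM the other scalings move log2 differences upward, so they could not turn the higher genes. Glucocorticoid responsive genes had a median of −0.24 at percentile 0.365, with the transcription factor gene Zbtb16 at −0.43 and the cell cycle inhibitor gene Cdkn1a at −0.55, against 0.75 for Sgk1. Their median turned to 0.037 with spike-in scaling, and their mean of −0.10 lay inside the random range.

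**Figure D1:**
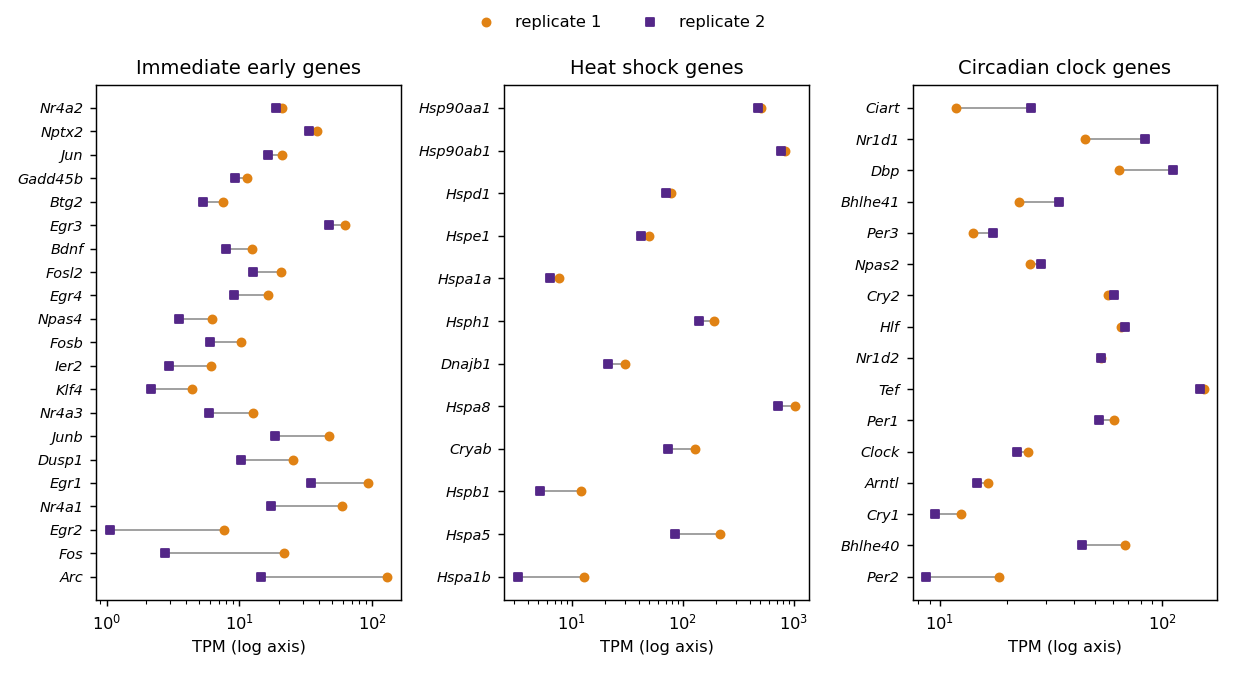
Level of each measured member of the immediate early, heat shock and circadian clock lists in replicate 1 (orange circles) and replicate 2 (purple squares), in TPM on a log axis. Every immediate early and heat shock gene was lower in replicate 2, or 20 of 21 and 9 of 12 with spike-in scaling, and the clock genes went in both directions.

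Neuronal and glial markers differed little between the animals. Upper layer markers were the only neuronal class outside the random range, with a median of 0.14 at percentile 99.4 and 7 of 10 members higher in replicate 2 (10 of 10 with spike-in scaling), led by the sodium channel subunit gene Scnn1a (0.36) and Rspo1 (0.31). Their mean, 0.11, lay inside the range. Percentiles were 91.8 for excitatory, 22.8 for inhibitory, 22.5 for interneuron subclass and 59.9 for deep layer markers, with the excitatory gene Neurod6 at −0.55 and the interneuron gene Calb2 at −0.49. Among glia they were 5.95 for astrocytes, 96.99 for oligodendrocytes, 25.9 for their precursors and 54.99 for microglia. Oligodendrocyte genes diverged, with Opalin at 1.06 and the myelin adhesion gene Mag at 0.55 but Ermn at −0.52, and the precursor gene Gpr17 stood at −0.54.

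Meningeal fibroblast markers had a median of 0.28 at percentile 99.5, with 8 of 9 members higher in replicate 2. With spike-in scaling 9 of 9 were higher, but so were 7 of 7 mural cell markers, whose list lay inside the range. Slc22a6, an anion transporter gene, and Aldh1a2, which makes retinoic acid, led the meningeal list at 0.51 and 0.44. Endothelial markers lay at percentile 2.91, with Itm2a at 0.65 and Ly6c1 at −0.40, mural cell markers at 95.2, with Vtn at 0.27, and red blood cell genes at 83.2. All 4 measured choroid plexus markers were lower in replicate 2 under each scaling, namely Ttr (−1.70), Prlr (−1.17), Kl (−0.66) and Clic6 (−0.33). Of the unmeasured members, the folate receptor gene Folr1 had 35 and 3 counts, whereas Otx2 had 21 and 51. Striatal markers lay at percentile 90.1, led by Rgs9 (0.30), and thalamic and habenular markers at 84.3, with the kinase gene Prkcd at 0.93 from 174 and 366 counts. The hippocampal, ependymal, olfactory bulb and hypothalamic lists had under 5 measured members and no percentile. Of these, the hippocampal gene C1ql2 differed by −0.21, the ependymal gene Foxj1 by −0.36, the olfactory bulb gene Doc2g by −0.46 and the hypothalamic peptide gene Trh by −1.77, from 89 and 28 counts.

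Most transmitter receptor and synapse lists lay inside the random range. Percentiles were 83.4 for GABA-A subunits, 86.1 for AMPA and kainate, 33.0 for NMDA, 96.6 for metabotropic glutamate and 41.7 for monoamine and acetylcholine receptors, 66.3 for sodium and HCN channels, 95.7 for presynaptic and 85.3 for postsynaptic density genes. Single members stood apart, with the serotonin receptor gene Htr1b at −1.09 and the postsynaptic scaffold gene Homer1 at −1.07 (11170 and 5850 counts), and Grm2, a presynaptic glutamate receptor, at 0.59. Voltage gated potassium channels had a median of 0.060 at percentile 99.7, with 9 of 15 members higher in replicate 2, among them Kcnc1 (0.10). With spike-in scaling 15 of 15 were higher, but so were 12 of 12 GABA-A subunits and 16 of 16 presynaptic genes. The mean of the potassium channel list, 0.022, lay inside the range. Neuropeptide genes had a median of −0.16 at percentile 1.13, with the corticotropin-releasing hormone gene Crh at −0.72 and the neurotensin gene Nts at −0.59, and 11 of 16 members lower in replicate 2. With spike-in scaling 4 of 16 were lower and the median was 0.11, and in the second table the median of −0.12 lay inside the range.

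Respiratory chain genes lay at percentile 16.4, neurodegeneration genes at 35.7 and interferon responsive genes at 64.0. Within them, the kinase gene Lrrk2 stood at −0.70, the interferon-inducible gene Lgals3bp at 0.24 and Cox5a at −0.22. Imprinted genes had a median of −0.13 at percentile 0.385, with 21 of 28 lower in replicate 2, against 5 of 28 and a median of 0.15 with spike-in scaling. Their mean of −0.11, and their median of −0.10 without the trend on length and GC content, lay inside the range. Zim1 and Peg10 led the lower members at −1.15 and −0.62, whereas Meg3 was at 0.69. The X linked list had a median of 0.15 at percentile 99.5. Xist stood at 0.16, Ddx3x, which escapes X inactivation, at 0.15 and Kdm5c at −0.43. The list's mean of 0.028 lay inside the range. In all, 10 of the 35 lists with a percentile lay outside the central 95%, and 6 of 35 did with the mean of members. Chance alone gives 1.75 for separate lists of genes that vary independently. Some lists share genes, such as Meg3, Rian, Igf2 and Sst. Members of a list may also vary together, unlike those of random lists, so 1.75 may be too low. The percentiles measure spread over genes, not over animals.

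**Figure D2:**
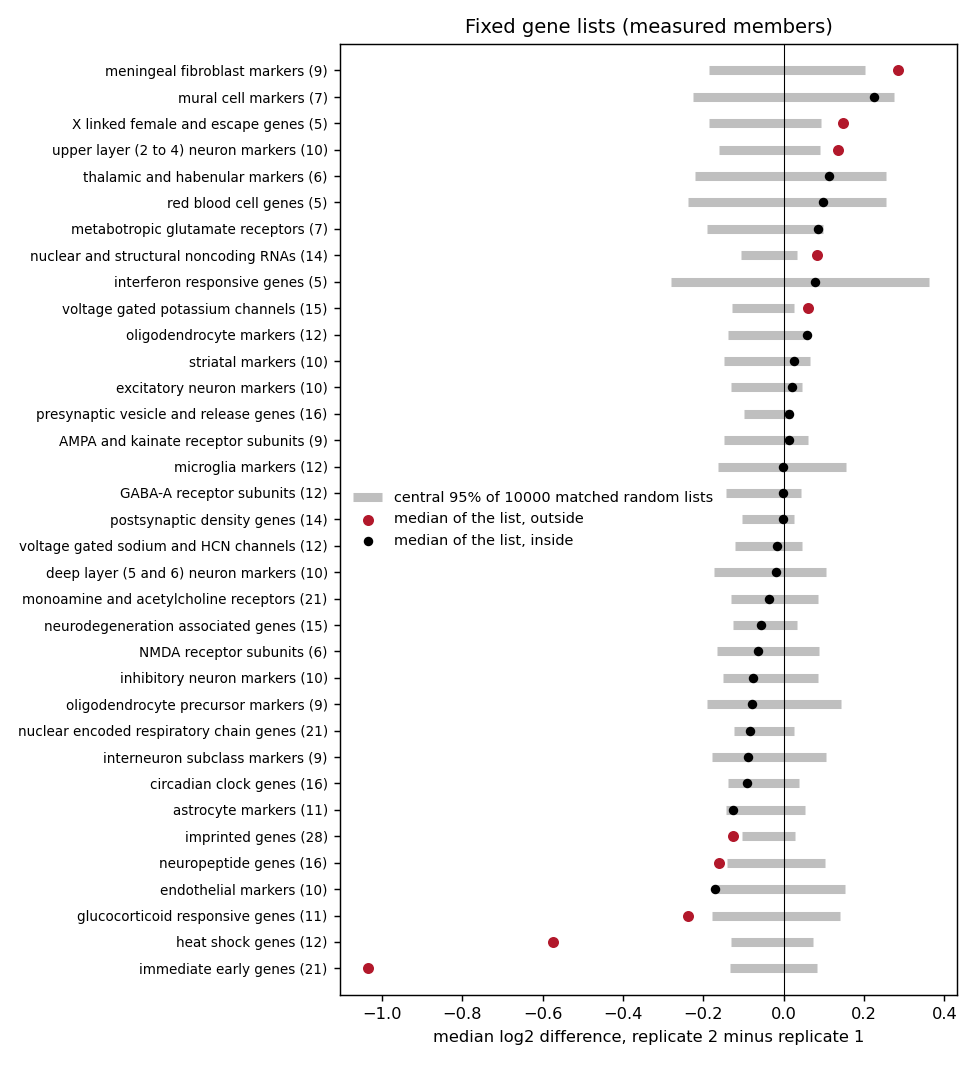
Median log2 difference (replicate 2 minus replicate 1, x axis) of the fixed lists with at least 5 measured members, with the number of members in brackets. Points are the medians, red where outside the grey bar that holds the central 95% of 10000 expression-matched random lists. Immediate early genes (−1.03) and heat shock genes (−0.57) lie furthest below their bars.

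Some noncoding RNAs of the nucleus were higher in replicate 2. Malat1 (log2 0.70), Neat1 (0.69), Meg3 (0.69), Snhg11 (0.66) and Miat (0.88) stood close together. Spike-in scaling adds 0.28 to every gene, so it could not turn these rises. The list of 14 measured nuclear and structural RNAs had a median of 0.082 at percentile 99.96, with 8 members higher and 6 lower (13 and 1 with spike-in scaling). Other members did not follow, with 7SL at −0.22, the ribozyme gene Rpph1 at −0.27, Pantr1 at −0.13, Gm26917 at −0.035, Rn7sk at 0.024 and Rian at 0.14. Rmrp has 2 gene entries at −0.39 and 0.26, so its division is uncertain. The share of TPM in transcripts annotated as retained introns was higher in replicate 2 for 4241 of the 6222 genes whose share differed (68.2%, Wilson 95% interval 67.0 to 69.3%), with medians of 7.54% and 9.46%. Genes are not independent, so that interval covers the count alone.

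Major transcript forms were mostly the same in both animals. Of 9657 genes with at least 5 TPM and 2 or more transcripts, 8543 (88.5%, Wilson 95% interval 87.8 to 89.1%) had the same leading transcript in both. The interval treats genes as independent, so it covers the count alone and not the spread over animals. Snap25-201 held 89.2 ± 0.728% of Snap25 (SD, n = 2), App-201 90.7 ± 1.49% of App, Mapt-204 74.6 ± 2.68% of the tau gene Mapt and Camk2b-209 91.4 ± 1.07% of the kinase gene Camk2b. Leads were narrower for Gria2-202 at 54.6 ± 6.65%, Syn1-202 at 53.1 ± 3.90% and Ank2-201 at 19.4 ± 2.39%. Over the 24 fixed isoform genes the median SD of the leading share was 2.67 percentage points and the largest was 8.54.

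Of the 24, the leading transcript differed between the animals for Bdnf, a neurotrophin, where Bdnf-209 held 36.8% in replicate 1 and 24.7% in replicate 2, and for Homer1, where Homer1-203 held 23.7% and 30.5%. The other 22 had the same leading transcript in both animals, among them Gria1, Gria3, Gria4, Cdc42, Ntrk2, Clta, Mbp, Gnas and Nrxn3. The second transcript table gave the same lead for 22 of the 24, the exceptions being Grin1 (Grin1-201 at 38.0 ± 3.24% against Grin1-205) and Dlg4 (Dlg4-203 at 44.0 ± 2.90% against Dlg4-201). Over all 9657 genes the tables named the same lead for 7931 (82.1%). The share of Mbp-211 was 64.6 ± 2.77% in the first table and 39.1 ± 2.18% in the second, so shares depend on the table more than on the animal there.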

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

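The tests of scaling for the immediate early genes (the scalings were planned, the bound was not), of time of day, of the nuclear RNA share, and of length and GC content were chosen only after the result was seen (for the immediate early genes, before the corrected value was). Reads of phiX174, a sequencing control that no comparison here uses, were present at a mean of 69 counts over the 2 libraries, above the 3 counts that a count of 0 allows. The labels give both animals the same strain, sex, age range and tissue, so no biological difference named by the design was tested.

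Immediate early genes were lower in replicate 2 in all 21 measured members, or in 20 with spike-in scaling. Scaling between libraries is argued against, since the highest median of the list over 4 scalings was −0.76, and a trend on length and GC content is too, since removing it left −1.09. As a hypothesis, lower MAP kinase signalling in the cortex of replicate 2 may account for it: 10 feedback genes of that pathway not looked at before, among them Spry2, Spred1, Dusp5 and Etv5, were all lower in replicate 2 (median −0.54) at the 0.0050 percentile of random lists, and each direction but that of Ier3, Dusp14 and Spry1 was the same with spike-in scaling. The list was added after other data were seen, among them Dusp4 (−1.70) and Dusp1 (−1.445), of the same family as Dusp5. Spry4 and Dusp6, related feedback genes also lower in replicate 2, are not on it. Members of such a list may vary together, unlike those of random lists, so the percentile is a weak check. Such feedback genes could fall with the immediate early genes under another cause, so their drop does not single out this pathway. Arousal, handling and the time between death and freezing were not tested and stay open.

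Clock genes of opposite phase stood apart between the animals. The 8 genes of the phase of Dbp and Nr1d1 had a median of 0.17 (5 higher, 3 lower in replicate 2) and the 5 of the opposite phase, Arntl, Npas2, Clock, Nfil3 and Cry1, −0.28 (1 higher, 4 lower, the median near 0 with the spike-in shift of 0.28), a difference that removing the trend on length and GC content left at 0.45, which argues against that trend. A different time of day at collection was not decided: the difference lay at percentile 99.99 of pairs of random lists, but the sets were drawn after most values had been seen, with Per1 (−0.19), Per2 (−1.11), Bhlhe40 (−0.62) and Cry2 (−0.014) in neither. A lower body temperature in replicate 2 is another open hypothesis, since the cold-induced gene Rbm3, not looked at before, lay at percentile 99.6 of genes of similar expression (log2 0.70) beside Cirbp (1.25). Collection times and temperatures are not given in the sources used here, and the temperature and time of day hypotheses do not exclude each other.

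Some nuclear noncoding RNAs were higher in replicate 2, with Malat1 at 0.70. A larger share of nuclear RNA in that library is not decided. The highest difference among Xist, Kcnq1ot1, Rian and Rn7sk, also nuclear, was 0.16, so the rise was not shared by all nuclear RNAs. These RNAs were chosen after the result was seen, and Neat1 (0.69), Meg3 (0.69) and Miat (0.88) rose with Malat1. Length or GC content is argued against, with the list at percentile 99.995 after correction. More unspliced RNA in the library of replicate 2 may contribute. Of genes whose share of retained intron transcripts differed, 68.2% had the higher share there in the first table and 68.4% in the second. Unspliced RNA is itself nuclear, so the retained intron shares do not separate it from a larger nuclear share. Whether they reflect transcription, RNA decay or sample handling was not tested.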

How the results depend on the processing

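Removal of the length and GC trend and the restriction to genes on which the tables give close differences were tests chosen only after the data were seen; the restriction left 132 genes over 2-fold. Of 245 list values under alternatives, 232 kept their side of the limits, 30 of them with the sign turned in lists inside the limits, and 3 outside the limits kept their side but turned their sign. Immediate early genes kept side and sign under all alternatives run (−1.24 to −0.76), as did heat shock genes (−0.72 to −0.30). Spike-in scaling, which adds 0.28 to every gene and so leaves percentiles nearly as they were, turned the medians of 18 lists, of which glucocorticoid (0.037), neuropeptide (0.11) and imprinted genes (0.15) lay outside the limits, and gave 339 genes over 2-fold, 292 higher and 47 lower. With the mean in place of the median, upper layer (0.11), glucocorticoid (−0.10), potassium channel (0.022), imprinted (−0.11) and X linked genes (0.028) came inside the limits and oligodendrocyte genes (0.13) passed them. Without the length and GC trend, imprinted genes (−0.10) came inside, and oligodendrocyte (0.043) and endothelial genes (−0.20) passed the limits. In the second table neuropeptide genes (−0.12) came inside. The cause was not tested. A minimum of 10 counts, which admits noisier genes, gave 862 genes over 2-fold (564 higher, 298 lower), and one of 200, with fewer genes, 48 (15 and 33). The median coding level was 15.2 TPM in the second table and 34.2 TPM rescaled to nuclear coding genes, a change built into that scale; without each replicate it was 16.2 to 16.8, and detection 15404 to 15910. Detection stayed within 1.5 times for every minimum and table tried. Pearson r was 0.982 with a pseudocount of 0.1 and 0.976 from 1 TPM up, and the coefficient of variation 14.2% without a filter. Leading transcripts were shared for 86.5% in the second table and 85.7% from 1 TPM up. By TPM, coding genes took 48.3%, mitochondrial genes 13.1% and spike-ins 0.525%. Depth limits genes under 50 counts, which have no difference here. No paired analysis was possible because the labels give 1 group.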

Other observations

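The chaperone test was planned before its 15 genes were looked at; the other values of this part were picked out only after they were seen, and none of the tests bears on them. Genes of protein folding in the endoplasmic reticulum were lower in replicate 2. The first 5 noticed, Hspa5 (also on the heat shock list), Pdia4, Pdia6, Sdf2l1 and the transcription factor gene Xbp1, had a median of −1.17. As a hypothesis, the lower level may be shared by the wider set: of 15 chaperone and secretory genes not looked at before, 14 were lower (8 with spike-in scaling), with a median of −0.53 at the 0.0050 percentile of random lists, led by Creld2 (−0.86), the calcium-binding chaperone gene Calr (−0.82) and Manf (−0.82). Ssr1 was the exception at 0.088, and 8 of the 15, including Hsp90b1 (−0.65), Pdia3 (−0.73) and Hyou1 (−0.53), lay below percentile 2.5 of genes of similar expression. With spike-in scaling, Dnajb9 (−0.23), Herpud1 (−0.19), Sec61b (−0.18), Sel1l (−0.18), Canx (−0.18) and Syvn1 (−0.071) turn to the other direction.

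Single genes lower in replicate 2 under every scaling were the feedback genes Spry4 (−1.40) and Dusp6 (−1.19), the collagen-modifying enzyme gene P4ha1 (−1.04) and the inositol transporter gene Slc5a3 (−0.97). The muscle genes Myh6 and Ttn were lower there too, Ttn by a log2 difference of −1.43. Higher in replicate 2 were the transferrin receptor gene Tfrc (0.83), the RNA-binding protein gene Hnrnpdl (0.81) and Leng8 (0.92).

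By annotated class, 72 of 106 antisense genes (median 0.18, percentile 99.8), 91 of 130 processed transcripts (0.16, percentile 99.97) and 118 of 198 lincRNAs (0.080, percentile 98.5) were higher in replicate 2. Inside the random range lay 393 genes of the annotation class TEC (percentile 23.8), 33 sense intronic genes (54.5) and 17 snoRNAs (95.1). Of 252 processed pseudogenes 161 were lower (median −0.10, percentile 0.005), a median whose sign turns with the spike-in shift of 0.28. Antisense genes and processed pseudogenes share sequence or place with other genes, so their counts are uncertain. The choroid plexus gene Kcne2 had 21 and 3 counts.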
